A study of Homo sapiens with 9 samples.

How the data were processed

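RNA was measured in 9 libraries of the H1650 cell line, 3 for each of the control, siMENA and siMENA11a siRNAs, collected on day 3 after transfection at 20 nM. Per the labels' protocols, total RNA was extracted with Qiazol and RNeasy columns with DNase treatment, 500 ng was depleted of ribosomal RNA with Ribo-Zero Gold, and stranded libraries were read as pairs of 75 bases on a NextSeq 500. Per the labels, the 3 libraries of a group are biological replicates, and groups were taken from the sample labels. The submitters' processing notes name the human build hg19. The aligner, the quantification tool and the annotation are not given in the sources used here.

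The authors deposited one table of FPKM values (fragments scaled by transcript length and library total) for 16630 genes in the 9 libraries. FPKM is scaled to the mapped fragments of each library, so a few abundant RNAs can shift all other values: RPPH1 and RMRP together took 10.7% to 14.6% of the FPKM sum, and the top 20 genes 19.7% to 23.9%. The sums ran from 558754 to 592930. The table holds no counts, so absolute depth is unknown. The steps between low values gave the depth relative to control replicate 1 as 1.47 and 1.59 for control replicates 2 and 3, 1.16, 1.45 and 1.45 for siMENA and 1.15, 1.29 and 1.36 for siMENA11a. The values are not whole reads per gene, so no counts were recovered and no count test was run.

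Part of the deposited FPKM values had lost their decimal point. No value had exactly 3 decimals, whereas 54179 had 4 and 1691 had 2, and 11543 values were whole numbers. Of the whole numbers, 16 lay near the other values of their gene (at most 1.37-fold above) and were kept. Together with 3 exact zeros these stayed as they stood, and the other 11524, which is 7.91% of the values, were divided by 1000. Of these, the ones in genes with at least 1 decimal value stood 198-fold or more, with a median of 1025-fold, above the rest of their gene. A further 237 genes had no decimal value to compare with, and their 2102 values were divided as well. Before the repair 694 values lay between 100 and 1000, and after it 6774 did. The repair touched 4868 genes. 1 value with a decimal comma was read as a decimal. Control replicate 1 had no missing value, while the other libraries had 411 to 592, so the table appears to list only genes listed in that library. The 1286 genes with a missing value were left out.

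Genes with a mean of at least 0.5 FPKM over the 9 libraries were tested, 13273 in all. Values were taken as log2(FPKM + 1) and compared with limma 3.58.1 in R 4.3.3, with one fit over all 9 libraries, group as the only term, 6 residual degrees of freedom and a mean-variance trend. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and adjusted p under 0.05 counted as passing. Comparisons were siMENA against control, siMENA11a against control and siMENA11a against siMENA, with a moderated F test over the 3 groups. For ENAH an exact permutation test was added. Before the data were examined, the groups, tests, alternatives, rule for naming genes and 37 gene lists with 716 genes were fixed, of which 634 genes were in the table. 33 lists with at least 5 tested members were compared with camera at a preset correlation of 0.01, adjusted over the lists, and repeated with an estimated correlation and with fry. The lists for fibroblast, leukocyte, endothelial and mitochondrially encoded genes had 3, 2, 3 and 0 members above the filter and were not tested. The highest means of the other cell types' markers were 72.1 FPKM for FBLN1, 4.12 for CD14 and 38.2 for EGFL7.

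Named genes are ENAH, LTBR, NFKB2 and RELB and, per comparison, the 10 with the largest rise and the 10 with the largest fall among genes that passed, had a mean of at least 1 FPKM and had every library of one group above every library of the other. Small RNA genes and clone-based names were passed over, and a few genes that met the rule are not reported here. Up to 4 passing members with the largest change are named from each list described. Members are named for lists that passed in a comparison and, in all comparisons, for the Ena/VASP, lymphotoxin, MHC class I and integrin lists. This restriction and the lists in the closing section were set after the values were seen.

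Replicate numbers are shared between groups in the labels. The deviations from the group means correlated between control and siMENA libraries of the same number at 0.124, 0.378 and 0.196, which by the rule used (each over 0.1) counts as pairing, between control and siMENA11a at 0.206, 0.425 and -0.0302, and between siMENA and siMENA11a at 0.0863, 0.309 and 0.0203. Libraries of different number ranged from -0.425 (control replicate 1 with siMENA11a replicate 2) to 0.321 (control replicate 1 with siMENA11a replicate 3). Control replicate 1 with siMENA replicate 3, at 0.113, also passed 0.1. The values therefore do not establish that the numbers mark matched batches. A fit with the replicate number as a block was an alternative. Pearson correlations of log2 values were 0.988 to 0.995 within groups and 0.978 to 0.990 between them. The first principal component held 40.0% of the variance and set siMENA (15.7 to 20.0) apart from siMENA11a (-20.5 to -16.1), with controls at -1.92 to 1.91. The third held 15.7% and set replicate 2 of every group (-17.1 to -6.88) apart from the other 6 libraries (2.33 to 10.3), so the libraries numbered 2 shared a shift.

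Other alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter and a filter of 2 FPKM, median-ratio scaling, quantile normalization, the moderation without trend or robust, a fit of the 6 libraries compared, a 2-fold minimum and leaving out each library. Alternatives chosen after seeing the data were missing values taken as 0, values not repaired, genes with a repaired value left out, a correction for GC content and length, leaving out replicate 2 of each group, and leaving out genes with a seed word. On simulated data built from the libraries, the test recovered 80.0%, 76.0% and 64.0% of genes changed by 0.5 on the log2 scale in the siMENA, siMENA11a and direct comparisons, and 8%, 14% and 8% at 0.25. False calls were 4.64%, 4% and 4.26%. Each simulation changed 50 of 13273 genes at each of 0.25, 0.5, 1 and 2, with independent noise between genes. That is a far smaller share than was called in the data, so these rates do not give the recovery there.

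Words of 7 bases were searched in annotated 3' UTRs (GENCODE 29, GRCh38, matched by gene name) of at least 30 bases, for 11930 genes, keeping words in at least 50 genes. Each word was ranked by the t of the difference in log2 fold change between genes with and without it in a linear fit. The fit also held the log length and the GC content of the 3' UTR and their squares. The t values were set against 100 permutations of the genes. On simulated data 5 of 5 words planted with a log2 shift of 0.15 came out first. The 2 strongest words of each siRNA group against control were used as its words. Median log2 fold changes with and without them were -0.0322 and 0.0607 under siMENA and -0.0485 and -0.004 under siMENA11a. These gaps are smaller than the planted shift, and smaller shifts were not simulated. For the count of words in the ENAH coding transcript, among the 10 strongest, a word that shared 5 bases in a row with a stronger one was left out, a step chosen after seeing the words. That transcript was 1 of 5 annotated coding ones, 3308 bases long, and does not hold CCAAGGA or CAAGGAA of exon 11a. Sequence found only in other ENAH transcripts was not counted. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used. Coordinates are given for GRCh38 only and were not converted.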

Results

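Gene expression was measured in H1650, an established human cell line of non-small cell lung cancer, on day 3 after transfection with 1 of 3 siRNA preparations at 20 nM. The control group received a pool of siRNAs that targets no human gene. The siMENA group received a pool against all transcripts of ENAH, the gene that encodes hMENA, a regulator of actin filament growth of the Ena/VASP family. The siMENA11a group received a mix of siRNAs that match exon 11a of ENAH, the exon that defines the epithelial isoform hMENA11a. Each group had 3 libraries of ribosome-depleted, stranded total RNA, described by the submitters as biological replicates. The table gave FPKM values, not read counts, for 16630 genes. Total depth is therefore unknown, but the steps between low values put the depth of the other 8 libraries at 1.15 to 1.59 times that of control replicate 1. Fold changes below are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and n = 3 libraries per group throughout.

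ENAH itself was lower in every library of both siRNA groups than in every control library. It measured 26.1, 30.04 and 26.1 FPKM in control replicates 1 to 3. The siMENA libraries held 4.43, 5.79 and 5.57 FPKM, a mean of 19.2% of control, and the siMENA11a libraries held 9.98, 11.0 and 10.3 FPKM, a mean of 38.1% of control. ENAH thus fell by 2.18 (SE 0.09) on the log2 scale under siMENA and by 1.31 (SE 0.09) under siMENA11a, with limma adjusted p of 6.41e-06 and 6.29e-05. Between the siRNA groups, ENAH was higher under siMENA11a by a log2 fold change of 0.87 (adjusted p 0.000112). An exact two-sided permutation test of the FPKM values gave p = 0.1 for each of these 3 comparisons, the smallest value that 3 against 3 libraries allow. Exon 11a lies at chromosome 1, positions 225504991 to 225505053 of GRCh38, on the minus strand, is 63 bases long and is part of 2 of the 9 annotated ENAH transcripts. The values are per gene, so the share of ENAH transcripts that contained exon 11a was not measured.

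**Figure D1:**
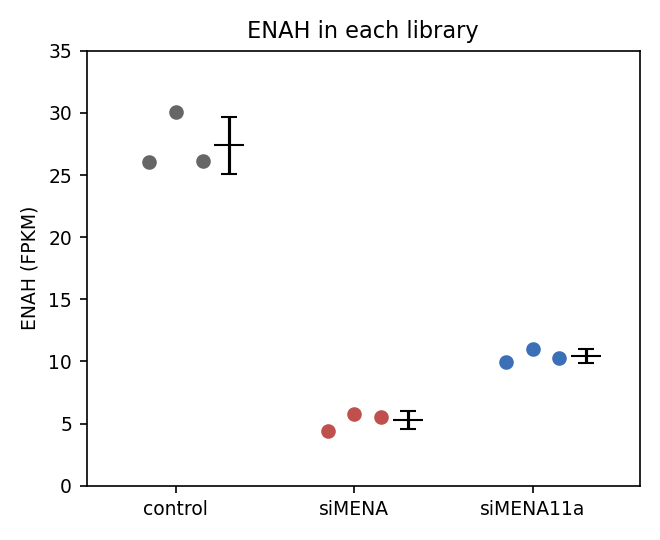
ENAH expression in FPKM (vertical axis) in each of the 9 libraries, grouped by siRNA; coloured points are libraries and the black bar with whiskers is the group mean with its SD (n = 3). The control libraries lie between 26.1 and 30.04 FPKM, the siMENA libraries between 4.43 and 5.79 and the siMENA11a libraries between 9.98 and 11.0.

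The first comparison asked which genes changed with the siRNA pool against all ENAH transcripts, siMENA against control. The largest rises were in DHRS2, a short-chain dehydrogenase, from 5.29 ± 0.89 to 41.2 ± 9.3 FPKM (mean ± SD), and in CGA, the shared alpha subunit of the glycoprotein hormones, from 2.22 ± 1.08 to 12.8 ± 2.0 FPKM. The peptidylarginine deiminase PADI3 rose from 3.23 ± 0.20 to 10.5 ± 0.6 FPKM and the sialomucin PODXL2 from 3.56 ± 0.25 to 9.20 ± 0.51 FPKM. KRT17, a keratin of basal and activated epithelium, DEFB1, an epithelial antimicrobial peptide, and the histone gene HIST1H2BA rose by log2 fold changes of 1.14, 1.10 and 1.34. The interferon-induced genes HERC5 and OASL rose by 1.14 each. Values for the read-through locus RPL36A-HNRNPH2 (log2 fold change 1.16, adjusted p 0.02) and for HIST1H2BA are uncertain because they share sequence with other genes, and the RPL36A-HNRNPH2 call ended when any one of control replicate 1, control replicate 2, siMENA replicate 1 or siMENA replicate 2 was left out (adjusted p 0.0583 to 0.08, against 0.0101 to 0.0979 over settings on repaired values).

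After ENAH, the largest falls were in CCK, which encodes the peptide hormone cholecystokinin, from 10.2 ± 1.7 to 2.80 ± 1.51 FPKM, and in S100A8, a calcium-binding protein of epithelial and myeloid cells, from 355.9 ± 5.8 to 126.6 ± 21.8 FPKM. The Notch ligand DNER fell from 17.9 ± 1.5 to 6.03 ± 1.25 FPKM. PRKAR2A, a regulatory subunit of protein kinase A, fell by 1.16 on the log2 scale, FAM96A, a factor of iron-sulfur cluster assembly, by 1.15 and CLCA2 by 1.10. The metallothionein MT1E fell by 1.32, but its near-identical paralogs make the value uncertain. ITGB1, the beta 1 integrin subunit, fell from 412.4 ± 28.3 to 186.1 ± 12.9 FPKM (log2 fold change -1.14, SE 0.08, adjusted p 2.45e-05). Among the integrins, 3 of 11 measured subunits rose and 4 fell: with ITGB1 fell ITGB8 (-1.08) and ITGAV (-0.68), while ITGA2 rose by 0.69. The integrin list as a whole did not pass (camera adjusted p 0.188, median -0.23), and 3 rose and 6 fell when adjusted over the list alone. Of the 10 genes with the largest falls, 6 carry one of 2 overlapping 7-base words, CAGAATA or AGAATAA, in their annotated 3' UTR, against 23.3% of all genes searched. Among them are CCK, S100A8, DNER, PRKAR2A and FAM96A. The words were picked as the strongest in this same comparison, so a higher share among its falls was built in. Among the integrins ITGB8 and ITGAV, which fell, and ITGA2 and ITGA1, which rose, also carry one, whereas ITGB1 does not.

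Genes of the type I interferon response rose or did not pass under siMENA. Of 36 measured members, 18 rose, none fell and 18 did not pass, with a median log2 fold change of 0.43 (camera adjusted p 2.15e-07; 21 rose and 1 fell when adjusted over the list alone). The call was lost with an estimated correlation between genes (adjusted p = 0.896 with an estimated correlation), which left none of the lists called in this comparison. HERC5, which attaches the ubiquitin-like protein ISG15 to its targets, went from 15.4 ± 3.3 to 35.8 ± 11.8 FPKM, and IFIT1, an inhibitor of viral RNA translation, from 39.9 ± 6.2 to 81.5 ± 21.0 FPKM. OASL went from 37.7 ± 9.3 to 85.0 ± 25.4 FPKM. IFIT3 reached a log2 fold change of 0.88 (adjusted p 0.0219) and lost its call when control replicate 1, control replicate 3, siMENA replicate 1 or siMENA replicate 2 was left out (adjusted p 0.0695 to 0.0774; 0.000374 to 0.0774 over settings on repaired values).

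Few mitotic or respiratory genes changed under siMENA. The G2/M and mitosis list passed with a median of -0.10 (camera adjusted p 0.0359), although only 2 of its 33 members fell, TOP2A, the DNA topoisomerase of replicating cells, by 0.71 and ANLN, a cytokinesis protein, by 0.41; 1 fell when adjusted over the list alone. Its adjusted p was 0.989 with an estimated correlation. Without control replicate 2 it was 0.465, with a median of 0.0186, and without siMENA replicate 3 it was 0.401. It also did not pass with fry, the GC and length correction or genes with a repaired value left out (7.48e-05 to 0.617 over settings on repaired values other than the estimated correlation). ANLN lost its call without control replicate 2 or 3 or siMENA replicate 1 or 3 (adjusted p 0.0717 to 0.0886; 0.00658 to 0.0886 over settings on repaired values). The list of nuclear-encoded oxidative phosphorylation genes had a median of 0.15 (camera adjusted p 0.0467), with 2 of 24 members higher, NDUFA4 by 0.27 and NDUFB8 by 0.22, and none when adjusted over the list alone. That list did not pass with the replicate number as a block (adjusted p 0.0579), with an estimated correlation (adjusted p = 0.896), with fry, a filter of 2 FPKM, median-ratio scaling or the GC and length correction, or without any one of control replicates 1 to 3 or siMENA replicate 1 (adjusted p 0.0513 to 0.14 for these libraries; 0.00324 to 0.157 over settings on repaired values other than the estimated correlation). Both genes lost their calls without control replicate 1 or 3 or siMENA replicate 1, and NDUFA4 also without siMENA replicate 2 and NDUFB8 without siMENA replicate 3 (adjusted p 0.0887 to 0.117 and 0.0557 to 0.133; 0.0117 to 0.117 and 0.0197 to 0.133 over settings on repaired values).

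In all, 2463 of 13273 genes tested, 18.6%, passed in siMENA against control, 1369 higher and 1094 lower, and 38 of them changed at least 2-fold. With median-ratio scaling of the libraries 56.2% of the calls were lower and with quantile normalization 52.0%, so the balance of higher and lower genes depended on the scaling. The count fell to 1346 without siMENA replicate 1, 1446 without control replicate 3, 1555 without control replicate 1 and 1572 without siMENA replicate 2.

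The second comparison asked which genes changed with the siRNAs against exon 11a, siMENA11a against control. The largest rises were in S100P, a calcium-binding protein common in carcinomas, from 2.45 ± 0.07 to 9.35 ± 2.41 FPKM, and BIRC3, an inhibitor of apoptosis that NF-kB induces, from 2.70 ± 0.31 to 8.59 ± 1.41 FPKM. KCNK15, a potassium channel, rose from 8.67 ± 0.58 to 23.6 ± 2.1 FPKM, and GATM, which makes the precursor of creatine, from 3.84 ± 0.55 to 10.4 ± 0.7 FPKM. UCHL1, a deubiquitinase, rose by 1.27 on the log2 scale, the bile salt exporter ABCB11 by 1.12, SDCBP2 by 1.09 and PNLIPRP3 by 1.09. OR7E91P rose by 1.10, but as a pseudogene of a large receptor family its value is uncertain. The T cell chemokine CCL5 rose from 69.1 ± 13.0 to 150.5 ± 41.1 FPKM (log2 fold change 1.09, SE 0.25, adjusted p 0.0152), a call that ended without control replicate 3 (0.97, adjusted p 0.0597; 0.000152 to 0.0597 over settings on repaired values).

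The largest fall was in LANCL1, a glutathione-binding protein, from 35.2 ± 2.3 to 9.30 ± 2.66 FPKM, followed by ITFG3, from 30.5 ± 1.5 to 10.6 ± 1.1 FPKM. GATSL3 fell by 1.41 on the log2 scale, PPP1R14C, an inhibitor of protein phosphatase 1, by 1.35 and C12orf75 by 1.32. EFTUD2, a GTPase of the spliceosome, fell from 32.7 ± 1.9 to 12.7 ± 1.0 FPKM (log2 fold change -1.30, SE 0.06, adjusted p 1.95e-05), the lysosomal protease CTSB from 62.4 ± 4.2 to 25.5 ± 2.8 FPKM, and LIMK1, the kinase that inactivates the actin-severing protein cofilin, from 20.3 ± 1.3 to 8.28 ± 0.56 FPKM. SUMF1, which activates sulfatases, fell by 1.15. Of the 10 genes with the largest falls, 9 carry the 7-base word CCAAGGA or CAAGGAA in their annotated 3' UTR, against 20.9% of all genes searched, and ENAH is the other one. Both words are part of the sequence of exon 11a. Of all genes called at least 2-fold lower and searched, 17 of 20 carry one. The words were picked as the strongest in this same comparison, so higher shares among its falls were built in. Their place in exon 11a was not used to pick them.

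**Figure D2:**
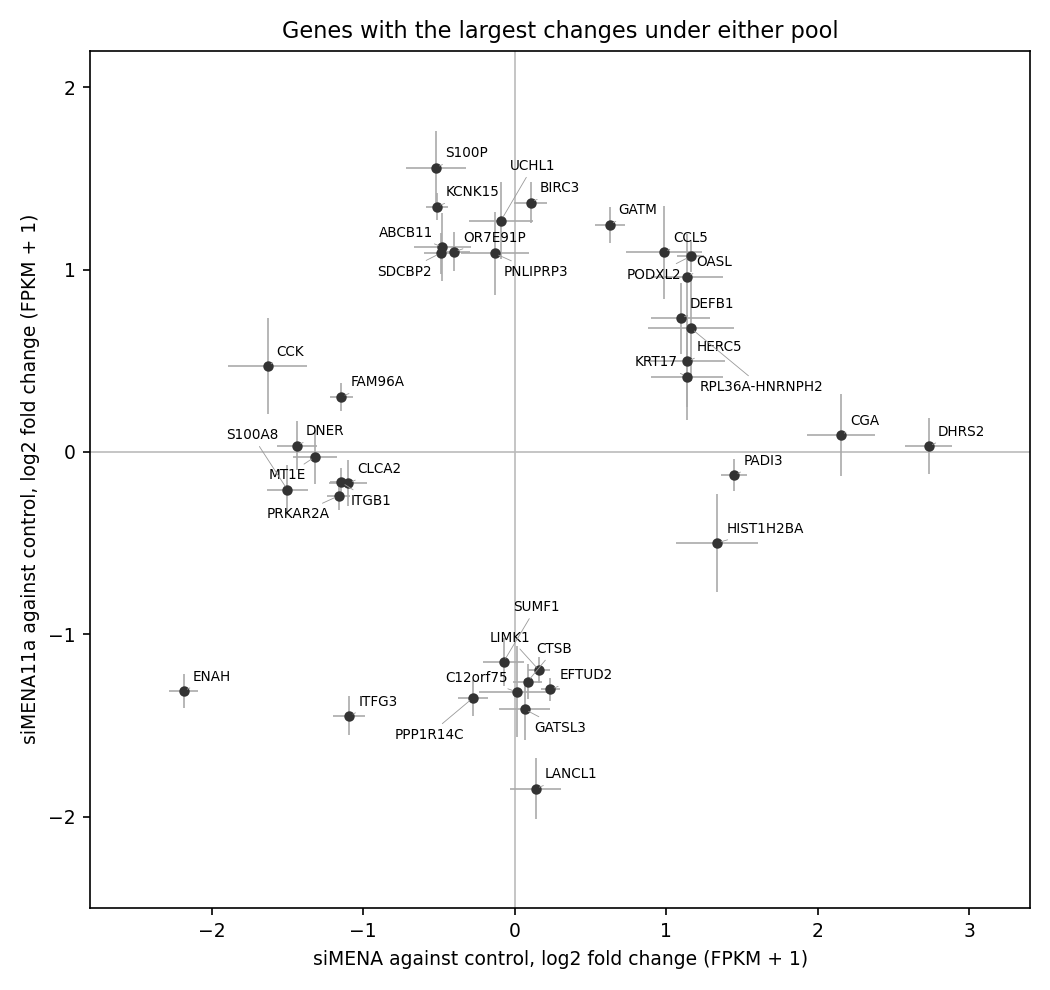
Log2 fold change (FPKM + 1) under siMENA (horizontal axis) and under siMENA11a (vertical axis), both against control, for the reported genes among the 10 with the largest rise and the 10 with the largest fall in either comparison; points are fitted values and bars are their SE. ENAH (-2.18 and -1.31) is low on both axes, DHRS2 (2.73 and 0.03) moved under siMENA and LANCL1 (0.14 and -1.85) under siMENA11a.

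Most measured cell cycle genes fell under siMENA11a. Of 34 genes of G1/S and DNA replication, 20 fell and none rose, with a median of -0.33 (camera adjusted p 1.82e-11; 28 fell when adjusted over the list alone; adjusted p = 0.319 with an estimated correlation). UNG, which removes uracil from DNA, fell from 40.2 ± 2.4 to 25.2 ± 1.0 FPKM and carries one of the exon 11a words. The replication factors CDC45, POLE2 and GINS1, which do not, fell by 0.53, 0.53 and 0.52 on the log2 scale. Of 33 genes of G2/M and mitosis, 18 fell and none rose, with a median of -0.43 (camera adjusted p 6e-10; 27 fell when adjusted over the list alone; adjusted p = 0.569 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell from 57.8 ± 7.9 to 36.4 ± 6.7 FPKM, and KIF20A, BUB1B and CENPF fell by 0.56, 0.56 and 0.54.

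Most cholesterol biosynthesis genes and some fatty acid synthesis genes fell. Of 23 measured genes of cholesterol biosynthesis and its control, 15 fell and none rose, with a median of -0.48 (camera adjusted p 1.06e-09; 16 fell and 1 rose when adjusted over the list alone; adjusted p = 0.211 with an estimated correlation). MVD, an enzyme of the mevalonate pathway, fell from 37.8 ± 1.2 to 21.1 ± 0.5 FPKM, the squalene epoxidase SQLE from 81.8 ± 3.2 to 52.99 ± 3.9 FPKM, MVK by 0.59 on the log2 scale and INSIG1, a sterol-dependent regulator that carries words of both siRNA groups, by 0.76. In the fatty acid synthesis list 4 of 13 fell and none rose, also when adjusted over the list alone (median -0.14, camera adjusted p 0.029; adjusted p = 0.241 with an estimated correlation): the desaturases FADS2, SCD and FADS1 by 0.78, 0.73 and 0.70, and ACLY, which makes cytosolic acetyl-CoA, by 0.31. FADS2, FADS1 and ACLY carry an exon 11a word. Without genes that carry words of either siRNA group the list had a median of 0.00615 and a camera adjusted p of 0.891 (0.00205 to 0.891 over settings on repaired values other than the estimated correlation). It also did not pass with genes with a repaired value left out (median -0.0182, camera adjusted p 0.858).

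Part of the unfolded protein response and respiration genes fell too. Of 18 measured members of the unfolded protein response, 9 fell and 1 rose, also when adjusted over the list alone, with a median of -0.19 (camera adjusted p 0.00263; adjusted p = 0.211 with an estimated correlation). They include the endoplasmic reticulum chaperones CALR, from 350.0 ± 7.1 to 226.1 ± 12.1 FPKM, and HSP90B1, from 327.7 ± 14.4 to 237.4 ± 11.5 FPKM, with SDF2L1 and CRELD2 down by 0.82 and 0.53 on the log2 scale. Of 24 nuclear-encoded oxidative phosphorylation genes, 10 fell and none rose, with a median of -0.19 (camera adjusted p 7.62e-07; 14 fell when adjusted over the list alone; adjusted p = 0.432 with an estimated correlation). COX5A fell from 131.2 ± 3.3 to 86.7 ± 13.2 FPKM and CYC1 from 230.8 ± 4.9 to 173.8 ± 9.8 FPKM, and NDUFA9 and ATP5O fell by 0.39 and 0.32.

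Part of the interferon, NF-kB and chemokine genes rose under siMENA11a. Of 36 interferon response genes 19 rose and none fell, with a median of 0.52 (camera adjusted p 2.91e-13; 21 rose when adjusted over the list alone; adjusted p = 0.211 with an estimated correlation). IRF9, a transcription factor that carries the interferon signal, rose with little spread, from 15.1 ± 0.6 to 29.4 ± 2.2 FPKM. OASL and IFIT2 reached 0.96 and 0.90, and both calls ended without control replicate 1 or 3 (adjusted p 0.063 to 0.07 for OASL and 0.0682 to 0.0753 for IFIT2, against 8.86e-05 to 0.07 and 0.000358 to 0.0753 over settings on repaired values). Among canonical NF-kB target genes 6 of 14 rose and 1 fell (median 0.25, camera adjusted p 0.00171; 7 rose and 1 fell when adjusted over the list alone; adjusted p = 0.319 with an estimated correlation). The cytokine IL6 rose from 25.9 ± 3.9 to 51.2 ± 6.1 FPKM and IL8 from 0.41 ± 0.17 to 1.24 ± 0.30 FPKM, while CCL20 and CXCL1 reached 0.53 and 0.75. CCL20 lost its call without control replicate 2 or siMENA11a replicate 1 or 3 (adjusted p 0.0564 to 0.0699; 0.0192 to 0.0699 over settings on repaired values). CXCL1 lost its call without any 1 library but control replicate 2 (0.0624 to 0.151; 0.00649 to 0.151). Of 5 measured lymphoid and T cell attracting chemokines, CCL5 and CCL28 were called higher, and 4 when adjusted over the list alone (median 0.49, camera adjusted p 0.00876; adjusted p = 0.211 with an estimated correlation). Without a filter on low values that list did not pass (adjusted p 0.0513, median 0.257). CCL28 (0.49, adjusted p 0.0335) lost its call without control replicate 2 or 3 or siMENA11a replicate 1 or 3 (adjusted p 0.0749 to 0.105; 0.00107 to 0.105 over settings on repaired values).

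Antigen presentation genes went both ways. Under siMENA, ERAP1 was the 1 called member of the MHC class I list, at 0.30, also over the list alone (camera adjusted p 0.805), and lost its call without siMENA replicate 1 (0.27, adjusted p 0.0538; 0.00338 to 0.0538 over settings on repaired values). Under siMENA11a 5 of 11 measured members rose and 2 fell, with 5 and 3 when adjusted over the list alone (median 0.31), and the list did not pass (camera adjusted p 0.286). The light chain B2M went from 1102 ± 71.5 to 1781 ± 196.0 FPKM (log2 fold change 0.69, adjusted p 0.00208) and the class I transactivator NLRC5 from 2.25 ± 0.13 to 3.64 ± 0.32 FPKM, both carriers of an exon 11a word, while CALR fell. In MHC class II presentation 3 of 5 measured members were called higher and all 5 when adjusted over the list alone (median 0.57, camera adjusted p 0.00152; adjusted p = 0.211 with an estimated correlation): HLA-DRA from 2.09 ± 0.52 to 4.48 ± 0.42 FPKM, the protease CTSS from 0.79 ± 0.03 to 1.93 ± 0.21 FPKM, and HLA-DQB1 at 0.51, a call lost without any 1 library but control replicate 1 (adjusted p 0.0628 to 0.115; 0.0187 to 0.115 over settings on repaired values). Of 10 immune checkpoint ligands 2 rose and 1 fell, with 4 and 1 when adjusted over the list alone (median 0.19, camera adjusted p 0.0411; adjusted p = 0.216 with an estimated correlation). CEACAM1 rose by 0.61, CD274, which encodes PD-L1, by 0.54 from 1.04 ± 0.07 to 1.98 ± 0.20 FPKM, and PVRL2 had -0.25. The CD274 call ended without control replicate 3 (0.52, adjusted p 0.0552; 0.00801 to 0.0552 over settings on repaired values). The PVRL2 call ended without control replicate 2 or 3 or siMENA11a replicate 1 or 3 (0.0928 to 0.13; 0.00956 to 0.13). The list did not pass with a filter of 2 FPKM, quantile normalization or genes with a repaired value left out, or without control replicate 1, control replicate 2 or siMENA11a replicate 1 (adjusted p 0.0502 to 0.217; 0.00211 to 0.217 over settings on repaired values other than the estimated correlation).

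Redox genes controlled by NRF2 rose or did not pass, and a few growth factor feedback genes rose. Of 17 NRF2 target genes 9 rose and none fell, with a median of 0.41 (camera adjusted p 1.83e-06; 12 rose when adjusted over the list alone; adjusted p = 0.211 with an estimated correlation). The cystine transporter SLC7A11 rose from 8.70 ± 1.57 to 20.0 ± 7.4 FPKM, AKR1C3 from 0.89 ± 0.22 to 2.68 ± 0.42 FPKM and GCLC, the rate-limiting enzyme of glutathione synthesis, from 5.91 ± 0.62 to 11.1 ± 0.7 FPKM. FTL, the ferritin light chain, reached 0.76, a call that ended without control replicate 3 (0.69, adjusted p 0.061; 0.00269 to 0.061 over settings on repaired values). Of 21 EGFR and MAPK feedback genes 4 rose and none fell, also when adjusted over the list alone (median 0.17, camera adjusted p 0.0167; adjusted p = 0.614 with an estimated correlation), namely the phosphatases DUSP6, DUSP5 and DUSP4 by 0.56, 0.33 and 0.30 and the EGFR ligand TGFA by 0.23. That list did not pass with fry, without replicate 2 of each group or without siMENA11a replicate 2 (for the last adjusted p 0.111, median 0.10; 0.00161 to 0.111 over settings on repaired values other than the estimated correlation). TGFA did not pass without control replicate 1 or without replicate 2 of each group (adjusted p up to 0.0593; 0.00439 to 0.0593 over settings on repaired values). The DUSP4 and DUSP5 calls also ended without replicate 2 of each group (adjusted p 0.0569 and 0.0601).

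LTBR, the lymphotoxin beta receptor, whose signal through non-canonical NF-kB drives the formation of lymphoid tissue, fell under siMENA11a from 52.7 ± 1.3 to 40.1 ± 2.2 FPKM (log2 fold change -0.39, SE 0.06, adjusted p 0.00196), lower in 3 of 3 libraries. Under siMENA it measured 52.0 ± 2.6 FPKM (-0.02, adjusted p 0.853), and the direct contrast of the siRNA groups was -0.37 (adjusted p 0.000986). As deposited, 2 of its 9 values stood 1000 times too high, and without their repair the log2 fold change under siMENA11a read 2.92 (adjusted p 0.677; 0.00169 to 0.0172 over the settings on repaired values). The transcription factors of the pathway did not pass: NFKB2 measured 8.83 ± 0.65 FPKM in control, 10.0 ± 0.3 under siMENA and 8.81 ± 0.96 under siMENA11a, and RELB 3.14 ± 0.35, 4.26 ± 0.38 and 4.39 ± 0.83 FPKM (adjusted p 0.0712 and 0.0536 against control). With the replicate number as a block RELB passed in both comparisons (adjusted p 0.0356 under siMENA and 0.0253 under siMENA11a; 0.0355 to 0.193 and 0.0122 to 0.151 over the settings on repaired values), and under siMENA also in a fit of the 6 libraries compared (0.0355). Under siMENA11a it passed as well with median-ratio scaling (0.0438), quantile normalization (0.0361), GC and length correction (0.0156) and without siMENA11a replicate 3 (0.51, adjusted p 0.0122). Of 14 measured members of the lymphotoxin and non-canonical NF-kB list, BIRC3 and BIRC2 were called higher and LTBR lower under siMENA11a, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p 0.719, median -0.00609 and mean 0.08). BIRC2 (0.18) lost its call without any 1 library but siMENA11a replicate 2 (adjusted p 0.0707 to 0.12; 0.0215 to 0.12 over settings on repaired values). Under siMENA 1 member fell, TNFRSF11A, the receptor RANK, by 0.66 (camera adjusted p 0.865), and it carries words of both siRNA groups. CXCL13 was not analysed here.

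Among 22 measured Ena/VASP family members and partners, 5 rose and 2 fell under siMENA (6 and 2 when adjusted over the list alone) and 1 rose and 4 fell under siMENA11a (likewise over the list alone), and the list passed in neither (camera adjusted p 0.668 and 0.565), with medians (0.14 and 0.00482) and means (-0.01 and -0.11) of opposite sign. Besides ENAH, LPP, a focal adhesion protein with words of both siRNA groups, fell by 0.51 under siMENA, a call that ended without replicate 2 of each group (adjusted p 0.0668), and SPTAN1 (0.38) and WASF2 (0.36) were called higher. The SPTAN1 call ended without any 1 library but control replicate 2 (adjusted p 0.056 to 0.0836; 0.00586 to 0.0836 over settings on repaired values). The WASF2 call ended without control replicate 1 or 2 or siMENA replicate 3 (0.0517 to 0.0712; 0.0101 to 0.0712). Under siMENA11a CAPZA1, the actin capping protein subunit, fell from 132.6 ± 4.6 to 77.5 ± 9.0 FPKM, and CFL1, cofilin, and DIAPH3, a formin, had -0.31 and -0.44. The CFL1 call ended without replicate 2 of each group and without control replicate 2 or 3 (adjusted p 0.0515 to 0.0883; 0.011 to 0.0883 over settings on repaired values). The DIAPH3 call ended without control replicate 2 or siMENA11a replicate 1 or 3 (0.0644 to 0.0727; 0.00369 to 0.0727). Among the 11 integrins 3 rose and 2 fell under siMENA11a, also when adjusted over the list alone (camera adjusted p 0.719). ITGB6 rose from 8.27 ± 1.5 to 16.7 ± 2.6 FPKM, ITGA2 by 0.63 and ITGA1 by 0.44, and ITGB5 fell by 0.44.

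**Figure D3:**
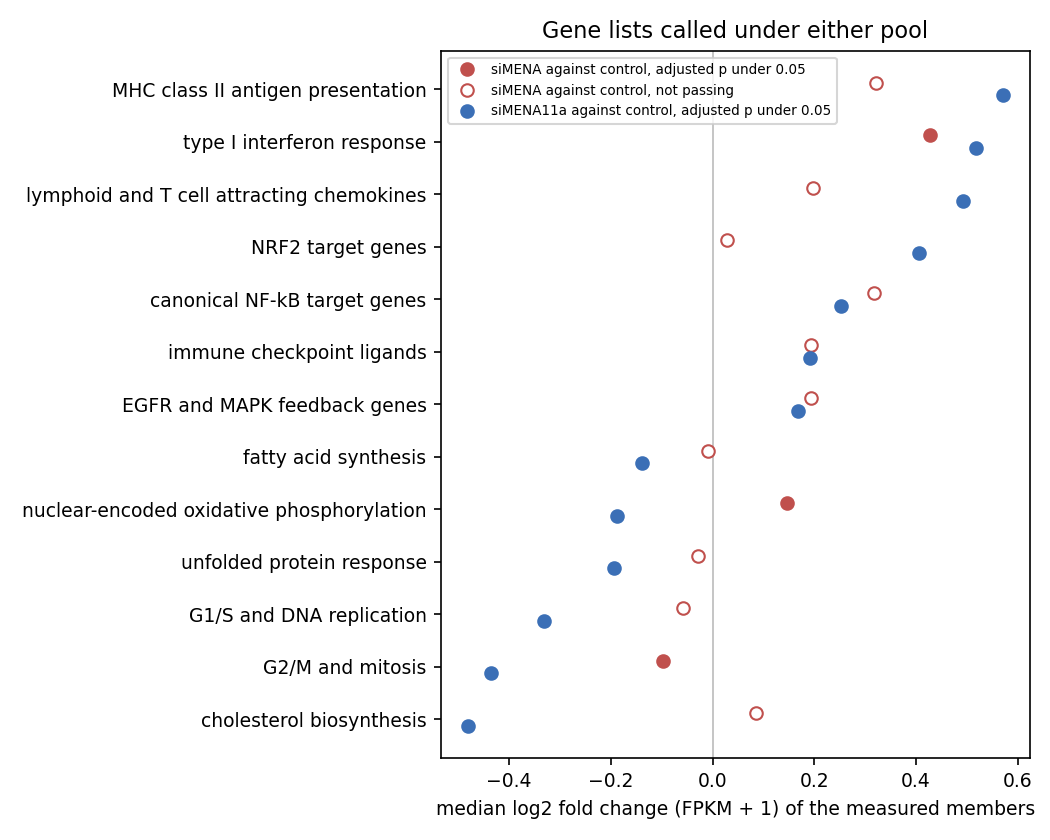
Median log2 fold change (FPKM + 1, horizontal axis) of the measured members of each gene list that passed in at least 1 of the comparisons with control; red circles are siMENA, blue circles are siMENA11a, and filled circles mark camera adjusted p under 0.05 with a preset correlation of 0.01. Interferon response genes lie right of 0 in both (0.43 and 0.52), and cholesterol biosynthesis lies at 0.09 under siMENA and -0.48 under siMENA11a.

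In all, 2583 genes, 19.5%, passed in siMENA11a against control, 1083 higher and 1500 lower, and 36 of them changed at least 2-fold. With median-ratio scaling 52.9% of the calls were lower and with quantile normalization 50.9%. Without control replicate 3 the count was 1493. All 13 lists that passed in this comparison were lost with an estimated correlation.

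The third comparison set the siRNA groups directly against each other. Here 4857 genes, 36.6%, passed, 1916 higher and 2941 lower under siMENA11a, and 89 differed at least 2-fold; with median-ratio scaling 49.8% of the calls were lower. DHRS2 was lower under siMENA11a by 2.70 on the log2 scale, CGA by 2.06, PADI3 by 1.58 and HIST1H2BA by 1.84, 4 genes that had risen under siMENA. MYL9, a myosin light chain of contractile fibres, measured 39.5 ± 12.2 FPKM under siMENA and 8.45 ± 5.99 under siMENA11a (-2.25, SE 0.45, adjusted p 0.00365), and carries an exon 11a word. S100A2, a keratinocyte protein, measured 41.0 ± 13.9 and 8.39 ± 2.26 FPKM. LANCL1 differed by -1.98, the collagen gene COL5A2, which carries words of both siRNA groups, by -1.55, and the histone genes HIST1H2AA and HIST3H2BB by -1.82 and -1.64. In the other direction CCK differed by 2.10, S100P by 2.08, KCNK15 by 1.86, ABCB11 by 1.60, SDCBP2 by 1.58, OR7E91P by 1.497, DNER by 1.47, FAM96A by 1.45 and SLC7A11 by 1.38. FEZ2, an adaptor of vesicle transport, measured 31.0 ± 1.3 FPKM under siMENA11a and 10.7 ± 1.1 under siMENA. CCK, DNER, FEZ2 and FAM96A carry CAGAATA or AGAATAA.

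Most respiratory and sterol genes and part of the cell cycle genes were lower under siMENA11a than under siMENA. Of 24 oxidative phosphorylation genes 20 were lower and none higher (median -0.33, camera adjusted p 8.51e-07; 21 when adjusted over the list alone; adjusted p = 0.77 with an estimated correlation). Among them were COX5A (-0.67) and CYC1 (-0.57). Of 23 cholesterol genes 17 were lower and none higher, also over the list alone (median -0.38, camera adjusted p 5.32e-06; adjusted p = 0.713 with an estimated correlation). They were led by MVD (-0.96), DHCR7 (-0.72), LSS (-0.71) and EBP (-0.70). In G1/S 17 of 34 were lower and 1 higher, also over the list alone (median -0.27, camera adjusted p 0.000711; adjusted p = 0.882 with an estimated correlation), with UNG (-0.97), POLE2 (-0.60), RFC3 (-0.55) and CHAF1B (-0.54). In G2/M 13 of 33 were lower and 1 higher, with 14 and 1 over the list alone (median -0.28, camera adjusted p 0.00886; adjusted p = 0.882 with an estimated correlation), with CDC20 (-0.73), KIF2C (-0.61) and AURKB (-0.57). This list did not pass with fry, with genes with a repaired value left out or without siMENA11a replicate 1 (adjusted p 0.0761 to 0.225; 1.7e-05 to 0.225 over settings on repaired values other than the estimated correlation).

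Part of the NRF2 target and hypoxia genes were higher under siMENA11a than under siMENA. Of 17 NRF2 targets 8 were higher and 1 lower (median 0.32, camera adjusted p 0.000594; 11 and 1 over the list alone; adjusted p = 0.713 with an estimated correlation), with AKR1C3 at 1.29 and PGD, an enzyme of the pentose phosphate pathway, at 0.69; HMOX1, heme oxygenase 1, went against the rest at -0.80. Of 22 hypoxia and glycolysis genes 7 were higher and 2 lower (median 0.07, camera adjusted p 0.0491; 8 and 2 over the list alone; adjusted p = 0.837 with an estimated correlation), with EGLN3 at 0.83, BNIP3L at 0.81, NDRG1 at 0.60 and VEGFA at 0.50. The hypoxia list did not pass without a filter on low values, with quantile normalization, with genes with a repaired value left out, with the replicate block (adjusted p 0.0548) or without siMENA11a replicate 1 or 3 (adjusted p 0.0863 and 0.0907; 0.01 to 0.386 over settings on repaired values other than the estimated correlation). The interferon list did not pass in the direct contrast (8 higher, 3 lower, median 0.09, camera adjusted p 0.107).

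Integrins and antigen presentation genes also differed singly. ITGB1 measured 367.0 ± 22.0 FPKM under siMENA11a and 186.1 ± 12.9 under siMENA (0.98, adjusted p 2.65e-05), and ITGB6, ITGB8 and ITGAV differed by 1.00, 0.86 and 0.73; 6 of 11 integrins were higher and 1 lower, also over the list alone (camera adjusted p 0.0598). B2M differed by 0.75, and the peptidase ERAP2 and CALR by -0.54 each, with 3 of 11 class I genes higher and 2 lower (3 and 3 over the list alone; camera adjusted p 0.673). Of the lymphotoxin list 4 were higher and 2 lower, also over the list alone (camera adjusted p 0.664), BIRC3 by 1.26 and TNFRSF11A by 0.63 against TRAF5 by -0.52. Of the Ena/VASP list 3 were higher and 10 lower, with 5 and 11 over the list alone (camera adjusted p 0.439), including EVL, a paralog of ENAH, at -0.55.

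Some genes were called in the same direction with both siRNA preparations. Across the 13273 genes the log2 fold changes against control had a Pearson correlation of 0.201 and a covariance of 0.0122. Both comparisons use the same control libraries, and simulated groups with no effect gave a correlation of 0.5 and a covariance of 0.00659. Shared controls and equal group sizes alone give that correlation, and changes particular to 1 siRNA group lower the observed one. The 2 correlations therefore cannot be compared. The observed covariance lay 0.00563 above the simulated one. Called genes with the same direction in both numbered 442, 219 higher and 223 lower, against 235 for independent lists of these sizes, a number that does not allow for the shared controls; with the replicate block they numbered 694. The same-direction genes numbered 253, 272 and 192 without control replicate 1, 2 or 3. They numbered 267, 292 and 374 without siMENA replicate 1, 2 or 3, and 306, 430 and 399 without siMENA11a replicate 1, 2 or 3. Whether the drops came from single libraries or from having fewer libraries was not tested. In the fit of all 9 libraries another 271 were called in opposite directions, against 244 for independent lists. Part of any excess may come from the shared controls, which are too few to split, and genes are not independent replicates. A moderated F test over the 3 groups called 5345 genes.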

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

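The counts over other splits of the libraries, and the tests of gene lists against 3' UTR words and against GC content and length, and the count of words without overlap, were chosen only after the results they measure were seen. The tests of word rank, of t against permutations and of at least 3 of the 10 strongest words in the ENAH coding transcript were set before. Groups of 3 libraries are too small for a test of single outlying libraries.

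The named genes and lists below were picked because siMENA and siMENA11a moved them in opposite directions against control, with all 3 comparisons past the threshold. The direct contrast (siMENA11a against siMENA, log2 scale), given in brackets, was part of the choice and is no separate test. Across all genes 271 were called in opposite directions, against 244 for independent lists. Some calls against control lay near the threshold, as for S100A2 (limma adjusted p 0.0319 under siMENA and 0.0485 under siMENA11a). Higher under siMENA and lower under siMENA11a were S100A2 (-2.13), HIST1H2AA (-1.82), HIST3H2BB (-1.64), COL5A2 (-1.55), EFTUD2 (-1.54), UNG (-0.97), PVRL2 (-0.69), ITGB5 (-0.64), ACLY (-0.55) and DDB2 (-0.53), a DNA damage recognition gene. Lower under siMENA and higher under siMENA11a were KCNK15 (1.86), SDCBP2 (1.58), OR7E91P (1.497), FEZ2 (1.46), FAM96A (1.45), ZMAT3 (1.18), an RNA-binding target of p53, and TP53INP1 (0.71). The nuclear-encoded oxidative phosphorylation list had a direct median of -0.33, from 0.15 under siMENA and -0.19 under siMENA11a, but all 3 calls were lost with an estimated correlation (adjusted p 0.896 under siMENA, 0.432 under siMENA11a and 0.77 in the direct contrast). Its siMENA call also ended in 9 of 21 other settings, among them the replicate block (adjusted p 0.0579) and leaving out any one of 4 libraries (adjusted p 0.0513 to 0.14), so its opposite movement is uncertain. The PVRL2 call under siMENA11a ended in 8 of 20 settings on repaired values. Calls of genes not named in that comparison were not run in these settings. Examples are EFTUD2 under siMENA (limma adjusted p 0.0306) and TP53INP1 under siMENA11a (0.0383). EFTUD2, UNG, PVRL2, ACLY and COL5A2 carry an exon 11a word, and FEZ2, FAM96A and ZMAT3 a word of the siMENA group. Against their direction, COL5A2 also carries a siMENA word and TP53INP1 an exon 11a word. S100A2, HIST3H2BB, ITGB5, DDB2, KCNK15 and SDCBP2 carry neither, and HIST1H2AA and OR7E91P were not searched. Histone and pseudogene values are uncertain because their sequences are shared.

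Genes lower under siMENA11a than under siMENA were enriched for a word of exon 11a. Of all 16384 words of 7 bases, the word with the strongest association in this contrast was CCAAGGA, which lies in exon 11a, so the best of its 57 words had rank 1 (t -12.8, against -5.27 for the lowest of 100 permutations). LANCL1, ITFG3, EFTUD2, CTSB and LIMK1 carry CCAAGGA or CAAGGAA, as do 25.7% of genes called lower in this contrast, against 19.5% of genes not called and 19.2% of genes called higher. These 2 words were picked in siMENA11a against control, where the shares were 33.2% of genes called lower and 19.3% of genes not called. B2M and NLRC5, which rose under siMENA11a, carry one too. This is what partial matches of the siRNA seed would give, so off-target silencing is a candidate explanation for part of the falls under siMENA11a, including that of LIMK1, a kinase of the actin pathway. Most called genes carry no such word, and loss of the isoform itself was not tested, since the mix was not split into single siRNAs.

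Genes lower under siMENA than under siMENA11a were enriched for a 3' UTR word. CAGAATA had t -14.4 in this contrast, beyond the lowest of 100 permutations (-4.87). The prediction set in advance also asked for at least 3 of the 10 strongest words in the ENAH coding transcript, and 3 lay there, CAGAATA among them. The strongest words overlap one another, so they do not count separately. Of the 4 left without overlap 1 lies in that transcript, as do 16.1% of all words (exact binomial p 0.505). With only 4 words, and only 1 of 5 coding ENAH transcripts used, this count cannot decide whether they come from the pool. S100A8, CCK, DNER, FEZ2, FAM96A, ITGB8 and ITGAV carry CAGAATA or AGAATAA, as do 40.8% of genes called lower under siMENA in this contrast, against 22.4% of genes not called and 14.7% of genes called lower under siMENA11a. These 2 words were picked in siMENA against control, where the shares were 49.6% of genes called lower, 21.8% of genes not called and 13.7% of genes called higher. ITGA2 and ITGA1, which rose under siMENA, carry one too. Seed matches of the total pool are a possible explanation that stays open, since the sequences of its siRNAs were not used here. ITGB1 carries neither word, and sites outside the annotated 3' UTR were not searched.

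Gene lists lower under siMENA11a (cholesterol biosynthesis, G1/S, G2/M and oxidative phosphorylation) were set against words in the members' own 3' UTRs and against GC content and length. Members without one of the words used kept 92.9% of the list median or more in all 4 lists. This argues against those words in the members as the whole cause. The medians after correction for GC content and length kept 89.1% or more, which argues against GC content and length as the whole cause. Only the strongest words of each siRNA group were used. In siMENA11a against control, other words also lay beyond the lowest of 100 permutations (t -4.85). Examples are TCCAAGG of exon 11a (-5.32) and GTTGTCA, from the opposite strand of exon 11a (-5.93). Members counted as without a word may carry these, so seed matches in general were not decided. All 4 list calls were lost with an estimated correlation between genes. A word in a regulator of these genes could still act on the lists, and this was not tested.

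The numbers of genes called were set against other splits of the libraries. Of 280 possible splits of the 9 libraries into 3 groups of 3, 100 were tried. Only 1, the real one, called as many genes by F test (5345, highest other 1245). Any other split, also of 6 libraries, leaves real group differences in the spread, so low counts there were in part built in. Some libraries also shared a shift across groups, so the libraries are not freely exchangeable. The real grouping thus stood out among the splits tried, but chance was not excluded. For 6 libraries there are 10 splits, too few for a share under 0.05: 2463 genes were called in siMENA against control, 2583 in siMENA11a against control and 4857 in the direct contrast, and the highest of the other splits called 1 gene in each.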

How the results depend on the processing

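Alternatives that used missing values as 0, unrepaired values, genes with a repaired value left out, a GC and length correction, replicate 2 left out in all groups or genes with a seed word left out were chosen only after the data were seen. On repaired values 153 of 180 named calls passed in every setting that tested their gene. The other 27 were lost in at least 1 setting, and 24 of these by leaving out 1 library. Leaving out genes with a repaired value or a seed word removed part of the named genes, so those calls were not tested there. The 2-fold minimum was not applied to single named calls. ENAH kept its direction and call in every setting run. Without repair, siMENA against control called 543 genes (279 higher, 264 lower), siMENA11a against control 556 (253, 303), the direct contrast 1703 (690, 1013), the F test 1625, and both siRNAs alike 84, with 1 list called under siMENA and 1 in the direct contrast. Values 1000 times too high widened the spread there by construction. Unrepaired log2 fold changes that changed sign were, under siMENA, CGA -0.87, LTBR 3.29, ITGB8 2.23, ITGA2 -2.62, ITGAV 2.63 and NDUFB8 -3.09. Under siMENA11a they were ITFG3 1.835, C12orf75 1.97, SUMF1 2.13, LTBR 2.92, CCL28 -2.81, ITGB5 2.86, TGFA -3.08, BUB1B 6.01, CENPF 2.77, CDC45 2.75, ACLY 3.00 and CRELD2 2.77. In the direct contrast they were B2M -2.57, ERAP2 2.735, ITGB1 -2.34, ITGB8 -2.45, ITGAV -2.58, BUB1B 6.03, NDUFA9 2.78 and CNN2 2.68. Without genes holding a repaired value, and so fewer genes, the counts were 1293 (730, 563), 1362 (605, 757), 2716 (1078, 1638), 2943 by F test and 231 shared, with 1 list under siMENA and 3 in the direct contrast. Without genes with a seed word they were 1318 (887, 431), 1395 (604, 791), 2880 (974, 1906), 3092 and 225, with 8 lists under siMENA, and 32.7% of siMENA calls were lower. Fatty acid synthesis under siMENA11a had camera's direction reversed, with medians of -0.0182 both unrepaired and without repaired genes and 0.00615 without seed-word genes. GC and length correction left 1 list under siMENA. Requiring 2-fold left 38 (15, 23), 36 (16, 20) and 89 (43, 46) genes. With an estimated correlation 0 lists passed in each comparison, and fry called 11 in the direct contrast. With the replicate block 694 genes were shared, and the counts were 3149, 3431, 5648 and 6372 by F test. It ended the calls of the oxidative phosphorylation list under siMENA and the hypoxia list in the direct contrast, brought RELB past the threshold in both comparisons with control, and changed no other call of a named gene or list. Splitting the libraries by replicate number called 8 genes. The siRNA differences stayed in the spread of that fit, so this count does not measure the replicate effect. Leaving out libraries gave 1346 to 2020 genes (650 to 1105 higher, 696 to 915 lower) under siMENA, 1493 to 2390 (593 to 964, 900 to 1426) under siMENA11a, 3626 to 4814 (1452 to 1855, 2174 to 2959) in the direct contrast, 4008 to 5388 by F test, 192 to 430 shared, and 1 to 4, 12 to 13 and 4 to 10 lists. Values near 0 that changed sign without passing were NFKB2 under siMENA11a (0.00911 with median-ratio scaling, 0.00535 with quantile normalization, 0.0588 with GC correction, 0.00743 without control replicate 2, 0.0359 without control replicate 3, 0.079 without siMENA11a replicate 3; -0.0582 to 0.079 leaving out libraries), LTBR under siMENA (0.0218 without siMENA replicate 1; from -0.0478 leaving out libraries) and RELB in the direct contrast (-0.0143 without replicate 2, -0.0309 without siMENA replicate 1, -0.0166 and -0.0608 without siMENA11a replicate 1 or 2; up to 0.159). The cause of the changes other than those from repair and fewer genes was not tested. Depth limits genes under 0.5 FPKM, which were not tested.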

Other observations

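The lists and genes in this part were chosen only after their values were seen. They concern siMENA11a against siMENA.

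Of 19 measured genes that serum response factor and its actin-regulated cofactors control, 8 were lower and 2 higher under siMENA11a, also when adjusted over the list alone (median -0.21, camera adjusted p 0.759, so the list did not pass). MYL9 differed by -2.25, CNN2, which carries an exon 11a word, by -0.63, and VCL, the focal adhesion protein vinculin, by -0.44. The tropomyosin TPM1 went the other way, from 75.03 ± 2.6 FPKM under siMENA to 126.1 ± 6.3 under siMENA11a (0.74, limma adjusted p 2.65e-05).

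Targets of p53 went both ways. Of 21 measured members 4 were higher and 6 lower, with 6 and 6 when adjusted over the list alone (median 0.02, mean -0.00407, camera adjusted p 0.759). ZMAT3 measured 9.16 ± 1.18 FPKM under siMENA and 22.0 ± 2.5 under siMENA11a, and it carries a word of the siMENA group. TP53INP1 differed by 0.71, whereas BTG2, an antiproliferative gene, differed by -0.95 and DDB2 by -0.53. Among 25 epithelial markers 3 were higher and 6 lower, also over the list alone (median 0.00308, camera adjusted p 0.582). CDH1, E-cadherin, measured 272.8 ± 12.4 FPKM under siMENA and 190.1 ± 10.0 under siMENA11a (-0.52), the protease PRSS8 differed by -0.68, and MAL2 and KRT7, both with a word of the siMENA group, differed by 0.78 and 0.48.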
